A study of Mus musculus with 12 samples.

How the data were processed

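RNA from mouse hearts was sequenced. The 12 libraries analysed came from 3 mice in each of 4 groups: wild-type (WT) mice given vehicle, WT mice given doxorubicin (DOX), PDE10A knockout (KO) mice given vehicle and KO mice given DOX, all on the C57BL/6J strain per the labels. DOX is an anthracycline used against cancer that damages the heart. PDE10A is a phosphodiesterase that breaks down the second messengers cAMP and cGMP. Per the labels' protocols, DOX was given as 1 bolus of 15 mg/kg and followed for 7 days, and libraries were made with a stranded mRNA kit. The protocols also describe a PDE10A inhibitor; no library used here is labelled with it. Mice are named here by the numbers in the titles, with KO vehicle mice as veh_3393, veh_3394 and veh_3395. The numbers differ between the groups, so the groups are not paired. KO vehicle mice have numbers from 3393 to 3395 and mice of the other groups numbers from 1 to 24. Whether KO vehicle mice were bred or handled apart is not given. If they were, that would be confounded with DOX in KO, KO under vehicle and the interaction.

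The authors deposited whole-number counts of reads per gene symbol, 1 file per library. Per the submitters' processing notes, the tools named were fastp 0.20.0, STAR 2.7.0f and Subread 1.6.4 with featureCounts. The genome build, the annotation and the strand setting are not given in the sources used here. How reads that match several places were counted is not given either, so counts of near-identical genes such as Hba-a1 and Hba-a2, and of genes with pseudogene copies, are uncertain. The counts covered 55453 symbols, of which 98.4% were found in GENCODE M21 on GRCm38. Positions quoted here come from that annotation, matched by symbol, and were used for location only.

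Counts were analysed as deposited in R 4.3.3. Genes were kept with edgeR's filterByExpr by group, which left 14757, and scaled with TMM factors. A negative binomial model with 1 mean per group was fitted to all 12 libraries with edgeR 4.0.16, and each comparison used the quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Sharing the spread among the 4 groups was chosen because 3 libraries against 3 leave few degrees of freedom. The comparisons were DOX against vehicle within each genotype, KO against WT within each treatment, and the interaction, which is the DOX effect in KO less that in WT. Standard errors were derived from the fold change and its F statistic. CPM values were computed from the deposited counts with TMM-scaled library sizes. The p-values for single genes measure the spread between separate animals. Those of camera also rest on the spread among genes, and Fisher's exact tests of calls near Pde10a count genes, not animals.

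Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Of 41 lists written before the data were examined, 39 had at least 5 tested genes and the other 2, with 3 tested genes each, were not tested. Camera with an estimated correlation and fry, which tests only a list's own genes, were alternatives. The genes named were chosen by a rule fixed before the data were examined. For each pairwise comparison it takes Pde10a, then the 8 highest and 8 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries. Xist, Y-linked genes and clone-type names were left out of that part. It adds up to 4 called members with the smallest p, in the direction most called members take, of each list that camera called or that had at least 3 called members, and 13 genes whatever their p. For the interaction it takes the 5 highest and 5 lowest called genes under the same limits, overlap aside. Genes outside the rule are said to have been chosen after their values were seen. Some results for single genes are not reported here.

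Alternatives fixed beforehand were DESeq2's size factors, no TMM scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, a fit of the 2 groups compared, the suffix 1 in the titles as a covariate, and leaving out each library in turn. A sex covariate was planned, but every library had Xist at or below 0.252 CPM and Ddx3y at or above 25.8 CPM, so 1 sex was present. Fits without the 2 libraries high in atrial transcripts, the overlap of the KO effect under vehicle with the DOX effect in WT, and a count near Pde10a with Tmem181a and its pseudogene counted once, were added after seeing the data. Comparisons that share a group were set beside 20 simulated draws of unchanged groups.

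Library totals ranged from 23846398 to 32921876 counts. Where a group had no count for a gene, a limit of 3 counts per library was used, which covers counting error only. The biological coefficient of variation was 17.5%. The test was tried on simulated counts for these libraries with 200 changed genes. For the DOX effect in WT, 74 of 100 genes with a 2-fold change and 97 of 100 with a 4-fold change were recovered among 14556 genes. For the DOX effect in KO these were 76 and 98 among 14583 genes, and for the interaction 47 and 86 among 14567 genes. These counts were drawn for each gene separately, without shifts of a library across many genes, so recovery in the real libraries may be lower. No pair of libraries agreed within sampling noise: the closest pair, KO vehicle mice veh_3393 and veh_3395, had a chi-square of 8.02 per gene.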

Results

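The series measured messenger RNA in mouse hearts by RNA sequencing, as read counts per gene. Hearts came from WT mice given vehicle, WT mice given DOX, KO mice given vehicle and KO mice given DOX, with 3 mice in each of the 4 groups. The labels imply 2 questions: what DOX does to the heart, and how the absence of PDE10A alters that. Library totals lay between 23846398 counts (KO DOX mouse 18) and 32921876 counts (WT DOX mouse 24). Mitochondrially encoded genes took 19.5% of the counts in WT vehicle mouse 2 and between 24.4% and 33.6% in the other libraries. On the first principal component, which held 28.9% of the variance, WT vehicle mouse 2 lay at -57.4 and WT DOX mice 22 and 24 lay at 41.6 and 40.4. WT DOX mouse 21 lay at 6.8, between KO DOX mice 20 (3.2) and 19 (17.3), and its counts had a chi-square of 17.6 per gene against KO DOX mouse 20 and of 71.4 and 74.1 against WT DOX mice 22 and 24. KO vehicle mouse veh_3394 and KO DOX mouse 18 lay apart on the second component, at -39.3 and -44.3.

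Pde10a, the targeted gene, had higher counts in the libraries labelled KO than in those labelled WT. It averaged 10.1 ± 1.54 CPM (SD, n = 3) in KO vehicle hearts and 8.62 ± 0.426 in KO DOX hearts. In WT hearts it averaged 2.08 ± 1.21 CPM with vehicle and 2.19 ± 0.465 with DOX. The log2 difference was 2.30 (SE 0.32, adjusted p = 0.0047) under vehicle and 1.98 (SE 0.31, adjusted p = 0.0243) under DOX, by edgeR's quasi-likelihood test. Every KO library lay above every WT library. The gene lies on chromosome 17 from 8525372 to 8986648 in GRCm38. The call under vehicle was kept in every fit that left out a library, and that under DOX was lost without WT DOX mouse 22 or 24 or KO DOX mouse 19 or 20 (adjusted p up to 0.109). The whole-gene count thus shows no loss of Pde10a transcript in the libraries labelled KO. It cannot show which exons were transcribed, so it does not settle whether the gene was disrupted. Genotypes here are those of the labels, "KO" stands for the libraries labelled KO throughout, and every direction between KO and WT rests on those labels. DOX did not move Pde10a past the threshold in WT (log2 0.09, adjusted p = 0.872) or in KO (log2 -0.23, adjusted p = 0.997).

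In WT hearts, DOX raised Myh7, the slow myosin heavy chain that the adult mouse ventricle holds at a low level, from 98.3 ± 36.7 CPM to 5220 ± 2770 CPM (log2 5.73, SE 0.64, adjusted p = 0.00468). Myh7 (chromosome 14, 54970684 to 54994626) belongs to the list of cardiac stress and fetal genes, of which 4 of 20 tested rose and 0 fell, or 5 and 1 adjusted over the list alone. Ankrd1 (log2 1.55, adjusted p = 0.0204) and Nrap (log2 0.70, adjusted p = 0.0326) also rose. The list passed camera with an adjusted p = 0.0228, and had an adjusted p = 0.717 with an estimated correlation. Its call was lost without WT vehicle mouse 1 (0.192) or WT DOX mouse 22 (0.0696). Nppa (log2 1.26, adjusted p = 0.283), Nppb (0.45, adjusted p = 0.403), Myh6 (-0.17, adjusted p = 0.282) and Acta1 (-1.46, adjusted p = 0.146) did not pass. Of 39 p53 targets, 8 rose and 0 fell, and the same numbers held adjusted over the list alone. They included Cdkn1a, the cell cycle inhibitor p21, from 44.5 ± 12.3 to 129 ± 47.2 CPM (log2 1.53, adjusted p = 0.0155), Eda2r (log2 1.17, adjusted p = 0.00941) and Trp53inp1 (log2 1.85, adjusted p = 0.0138). The p53 list had a camera adjusted p = 0.0186, and an adjusted p = 0.391 with an estimated correlation, and its call was lost without WT vehicle mouse 1 (0.153). Of 32 cell cycle genes, 10 fell and 0 rose, or 12 and 0 adjusted over the list alone, among them the proliferation marker Mki67 (log2 -2.57, adjusted p = 0.00887) and Top2a, a topoisomerase that DOX poisons (log2 -2.42, adjusted p = 0.0165). That list had a camera adjusted p = 6.73e-05, and an adjusted p = 0.556 with an estimated correlation.

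Transcripts of several blood and stromal cell types moved in WT hearts. Of 9 neutrophil markers 8 rose, or 8 adjusted over the list alone, including S100a8 (log2 4.03, SE 0.56, adjusted p = 0.00858), S100a9 (log2 3.41, adjusted p = 0.00858) and Cxcr2 (adjusted p = 0.00858). S100a8 went from 0.45 ± 0.142 to 7.36 ± 4.52 CPM. The neutrophil list had a camera adjusted p = 2.91e-06, and an adjusted p = 0.556 with an estimated correlation. All 8 MHC class II genes fell, also adjusted over the list alone. H2-Ab1 went from 45.8 ± 21.4 to 5.59 ± 7.3 CPM (log2 -3.05, adjusted p = 0.0187), and Ciita, the master regulator of these genes, had log2 -3.22 (adjusted p = 0.0168). H2-Ab1 stood at 14 CPM in WT DOX mouse 21 and at 1.57 and 1.18 CPM in mice 22 and 24, and without mouse 21 its log2 value was -5.07. That of Ciita without mouse 21 was -5.98, but it rests on 1 and 0 counts in mice 22 and 24 and is not a measured size. Both calls were lost without WT vehicle mouse 2 or WT DOX mouse 22 or 24 (adjusted p up to 0.0704). The MHC class II list had a camera adjusted p = 9.06e-07, and an adjusted p = 0.556 with an estimated correlation. Of 22 endothelial markers 11 fell and 0 rose, or 14 and 1 adjusted over the list alone, led by the apelin receptor Aplnr (log2 -3.09, adjusted p = 0.00887) and Egfl7 (log2 -0.96, adjusted p = 0.0101). Its camera adjusted p was 4.31e-05, and it had an adjusted p = 0.556 with an estimated correlation. Smooth muscle and pericyte markers fell in 6 of 17, including Kcnj8 (log2 -0.61, adjusted p = 0.00951), with a camera adjusted p = 0.0191 and an adjusted p = 0.556 with an estimated correlation, and the call was lost without WT vehicle mouse 1 (0.142). Of 9 erythroid markers 5 fell. Hba-a2 and Hbb-bt had no count in any WT DOX library, against 1578 and 713 counts summed over the WT vehicle libraries, so they were at least 197-fold and 89-fold lower. Hba-a1 and Hba-a2 are near-identical, as are Hbb-bs and Hbb-bt, and counts can be split between them. The erythroid list had a median log2 of -5.10, fitted or with genes at their limit, a camera adjusted p = 0.00761 and an adjusted p = 0.608 with an estimated correlation.

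Nuclear-encoded subunits of oxidative phosphorylation (OXPHOS) fell together in WT hearts. Of 77 tested, 60 fell and 0 rose, or 65 and 0 adjusted over the list alone, with a median log2 of -0.60. On log2 CPM the median was -0.59, and -0.36 after each library was adjusted for annotated exon length and GC content. Cox7a1, a heart and muscle subunit of cytochrome c oxidase, went from 941 ± 300 to 298 ± 141 CPM (log2 -1.66, adjusted p = 0.01), and Uqcr11 had log2 -1.08 (adjusted p = 0.0107). The list had a camera adjusted p = 2.25e-21, and an adjusted p = 0.608 with an estimated correlation; fry gave 0.0291. The list's median stood 0.72 above the mean of all libraries on the log2 scale in WT vehicle mouse 2, 0.35 in mouse 3 and 0.11 in mouse 1. Glucocorticoid targets rose in 7 of 20, including Hif3a (log2 2.23, adjusted p = 0.00887) and Fkbp5 (log2 1.91, adjusted p = 0.0128). That list had a camera adjusted p = 0.0101, and an adjusted p = 0.608 with an estimated correlation, and its call was lost without WT vehicle mouse 1 (0.0671) or WT DOX mouse 22 (0.128). The other lists called had camera adjusted p-values of 0.0419 or lower. Atrophy and ubiquitin ligase genes were higher (2 of 23 rose, adjusted p = 0.717 with an estimated correlation). Extracellular matrix genes were lower as a list (median -0.47) although 3 of 37 rose and 2 fell, and Thbs2 rose by log2 1.68 (adjusted p = 0.0103). The adjusted p was 0.979 with an estimated correlation. Fibroblast markers (3 of 21 fell and 1 rose, adjusted p = 0.943 with an estimated correlation) and heat shock genes (4 of 18 fell and 1 rose, adjusted p = 0.858 with an estimated correlation) were lower. The call of the heat shock list was lost without WT vehicle mouse 2 (camera adjusted p = 0.266) or WT DOX mouse 21 (0.0516), 22 (0.063) or 24 (0.0554), and that of the extracellular matrix list without WT vehicle mouse 1 (0.0584) or 2 (0.125) or WT DOX mouse 24 (0.199). The fibroblast call was lost without WT vehicle mouse 2 (0.077) or WT DOX mouse 24 (0.0835), and the atrophy call without WT DOX mouse 22 (0.0766). Genes of oxidative stress defence rose in 8 of 31 and fell in 2, with Gsta3 at log2 1.29 (adjusted p = 0.00858), and the list did not pass camera (adjusted p = 0.494). Genes of iron handling and ferroptosis rose in 6 of 23, with Cp, ceruloplasmin, at log2 1.12 (adjusted p = 0.00911), and that list did not pass either (adjusted p = 0.088).

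In all, 2743 of 14757 genes passed the threshold for DOX in WT hearts, 1386 higher and 1357 lower; without TMM scaling these were 1845 higher and 941 lower. The count was 5575 with limma-voom, 1595 with the title suffix as a covariate and 20 in a fit of the 2 WT groups. It was 4188, 513 and 742 without WT vehicle mice 1, 2 and 3, and 185 and 183 without WT DOX mice 22 and 24. Of 107 genes the rule names and the test called, 20 kept their call whichever library was left out, among them Chil3, Myh7, S100a8, S100a9, Irs2, Aplnr, Cryba4, Eda2r, Trp53inp1, Hk1, Thbs2, Gsta3, Cp, Hif3a, Nr4a1, Mki67, H2-DMa, Cxcr2 and Kcnj8. The other 87 lost it in at least 1 such fit: 85 without WT DOX mouse 22, 83 without mouse 24, 67 without WT vehicle mouse 2, 59 without mouse 3, 9 without mouse 1 and 3 without WT DOX mouse 21. In the fit of the 2 WT groups, 7 of the 106 named genes it held kept their call. With the title suffix as a covariate 71 of 107 kept it.

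**Figure D1:**
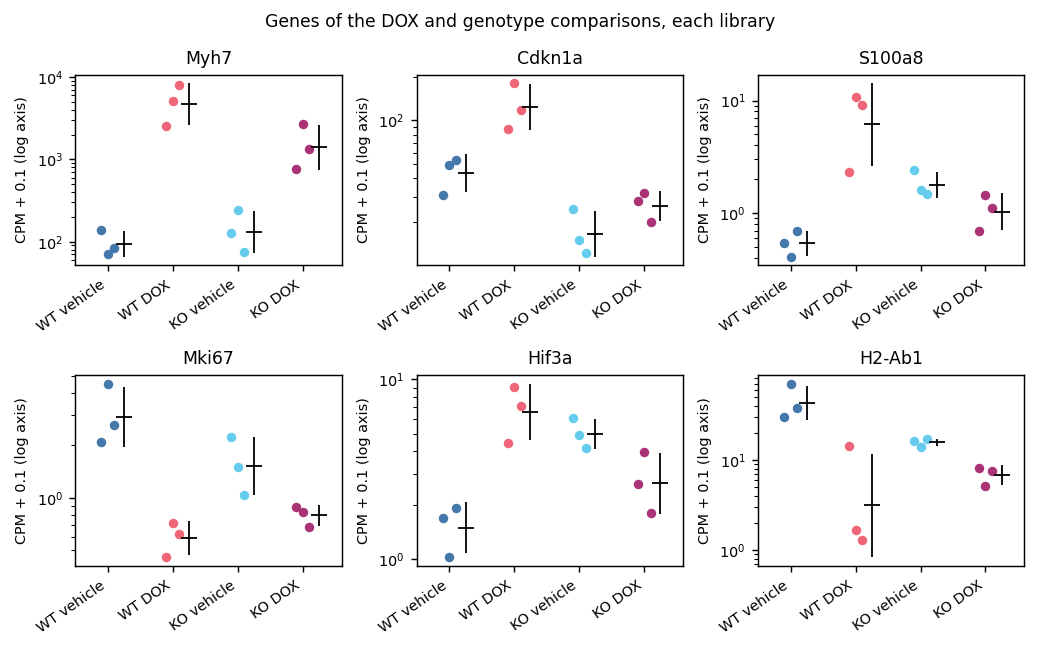
CPM plus 0.1 on a log axis for Myh7, Cdkn1a, S100a8, Mki67, Hif3a and H2-Ab1, with each dot 1 of 3 libraries per group and the black mark and bar the mean and SD of the log values. Myh7 averaged 98.3 CPM in WT vehicle and 5220 in WT DOX hearts, and 148 in KO vehicle and 1600 in KO DOX hearts.

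In the hearts labelled KO, 2 genes passed the threshold for DOX against vehicle. Slc41a3, a magnesium transporter, went from 22.4 ± 3.79 to 52.8 ± 10.8 CPM (log2 1.24, SE 0.17, adjusted p = 0.0493). Icosl, a costimulatory ligand of T cells, went from 16.5 ± 2.52 to 7.59 ± 1.18 CPM (log2 -1.13, SE 0.15, adjusted p = 0.0493). In WT hearts Slc41a3 averaged 54.7 CPM with vehicle and 68.4 CPM with DOX, and Icosl 9.44 and 8.1 CPM. For both genes KO DOX hearts thus lay near WT hearts, and KO vehicle hearts lay apart. A response to DOX cannot be told apart there from a trait of the KO vehicle mice. Myh7 stood at 148 ± 84.4 CPM with vehicle and 1600 ± 1000 CPM with DOX, and each KO DOX library (761, 2710 and 1330 CPM) lay above each KO vehicle library (129, 240 and 74.7 CPM), yet it missed the threshold (log2 3.44, SE 0.57, adjusted p = 0.132). Cdkn1a (log2 0.60, adjusted p = 0.997), Top2a (-1.47, adjusted p = 0.697) and Nppb (1.51, adjusted p = 0.373) did not pass either. No member of any list passed over all genes, and camera called 13 lists, each with an adjusted p of 0.0448 or lower. MHC class II genes were lower (median log2 -1.08, 0 of 8 called, 2 adjusted over the list alone, adjusted p = 0.721 with an estimated correlation). Inflammatory cytokine and acute phase genes were lower (median -0.56, 3 of 22 adjusted over the list alone, adjusted p = 0.538 with an estimated correlation). Glucocorticoid targets were lower (median -0.29, 3 of 20 adjusted over the list alone, adjusted p = 0.721 with an estimated correlation). Nuclear OXPHOS subunits were lower by a median of -0.10 (adjusted p = 0.902 with an estimated correlation), cell cycle genes by -0.21 (adjusted p = 0.728 with an estimated correlation) and heat shock genes by -0.25 (adjusted p = 0.721 with an estimated correlation). Interferon response (-0.24), macrophage and monocyte (-0.29) and neutrophil (-0.83) lists were lower, each with an adjusted p = 0.728 with an estimated correlation. The erythroid list was lower (-0.40, adjusted p = 0.778 with an estimated correlation). Cardiac stress and fetal genes (0.15, adjusted p = 0.728 with an estimated correlation), p53 targets (0.15, adjusted p = 0.381 with an estimated correlation) and lymphatic and mesothelial markers (0.43, adjusted p = 0.88 with an estimated correlation) were higher. The lymphatic and mesothelial list stood at 1.46, -0.82 and 0.49 in KO DOX mice 18, 19 and 20 and at -0.39, 0.80 and -0.59 in KO vehicle hearts, as the median log2 distance from the WT vehicle mean. KO DOX mouse 18 was also 1 of the 2 libraries high in atrial transcripts. Without it the calls of the lymphatic and mesothelial (camera adjusted p = 0.908), erythroid (0.789), cardiac stress and fetal (0.142), nuclear OXPHOS (0.142) and p53 (0.0915) lists were lost. Without KO vehicle mouse veh_3393 those of the erythroid (0.295), lymphatic and mesothelial (0.214), cardiac stress and fetal (0.103), p53 (0.0732) and neutrophil (0.0729) lists were lost. The lymphatic and mesothelial call was also lost without KO vehicle mouse veh_3395 (0.26) or KO DOX mouse 20 (0.17), and the cardiac stress and fetal call without veh_3395 (0.143). Hemoglobin transcripts summed to 13 counts in KO DOX mouse 18, and to 5478 and 1497 in KO DOX mice 19 and 20. The KO vehicle libraries held 6310, 3274 and 1057, and the WT DOX libraries 6, 1 and 2.

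For the DOX effect in KO, 789 genes had an unadjusted p below 0.05, where 738 were expected by chance. The count of calls was 66 with DESeq2, 88 with limma-voom, 309 without a filter, and 0 without TMM scaling, with the title suffix as a covariate or in a fit of the 2 KO groups. It was 1 without KO vehicle mouse veh_3394 and KO DOX mouse 18, 4 without KO DOX mouse 18, and 0 without any other KO library.

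The DOX effects in WT and KO, which share no library, had a Pearson r of 0.143 and a Spearman rho of 0.256 across 14757 genes, which are not independent replicates. The Pearson r was 0.0398 without KO vehicle mouse veh_3394 and 0.0903 without KO DOX mouse 19. Of the 2743 genes called in WT, 2071 (75.5%) had the same sign in KO. Their median size was 0.61 in WT and 0.10 in KO, counted in the WT direction, and the slope of KO on WT was 0.103. These genes were chosen on their WT values. Of the 789 genes with an unadjusted p below 0.05 in KO, 498 (63.1%) had the same sign in WT, with a slope of WT on KO of 0.115. Across all genes the median size of the log2 fold change was 0.296 in WT and 0.12 in KO.

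**Figure D2:**
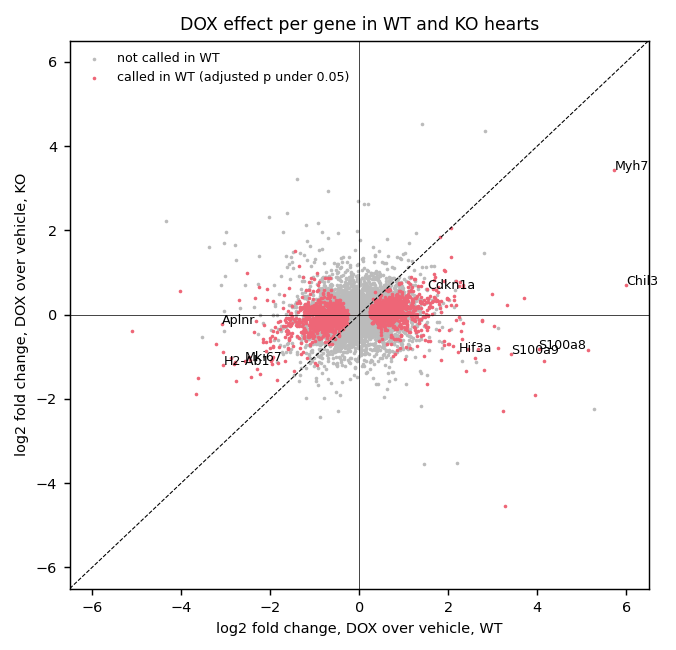
Log2 fold change of DOX over vehicle in WT (horizontal axis) and KO hearts (vertical axis), 1 dot per gene, with the 2743 genes called in WT in red; 7 genes lie outside the axes and the dashed line marks equal effects. Myh7 lies at 5.73 in WT and 3.44 in KO, while S100a8 lies high in WT and below 0 in KO.

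Under vehicle, the hearts labelled KO differed from those labelled WT in 425 genes, 264 higher and 161 lower. Arntl, which encodes the clock activator BMAL1, stood at 1.31 ± 0.532 CPM in KO and 11.6 ± 2.6 CPM in WT (log2 -3.15, SE 0.41, adjusted p = 0.00339). Of 19 circadian clock genes 5 were higher and 2 lower, or 11 and 4 adjusted over the list alone, among the higher ones Hlf (log2 1.23, adjusted p = 0.0032), Tef (1.03, adjusted p = 0.0144) and Per3 (1.18, adjusted p = 0.0193). The clock list had a camera adjusted p = 0.00988, and an adjusted p = 0.927 with an estimated correlation. Of 33 genes of calcium handling and ion channels 5 were higher and 0 lower, or 9 and 0 adjusted over the list alone. They included the potassium channel gene Kcnh2 (log2 0.77, adjusted p = 0.00483) and the ryanodine receptor gene Ryr2 (0.88, adjusted p = 0.0217). The list had a camera adjusted p = 0.0073, and an adjusted p = 0.855 with an estimated correlation. Of 22 endothelial markers 4 were lower, or 11 adjusted over the list alone, including the tight junction gene Cldn5 (log2 -2.11, adjusted p = 0.0131) and Kdr, a VEGF receptor (-0.97, adjusted p = 0.0447). Their camera adjusted p was 7.64e-06, and they had an adjusted p = 0.855 with an estimated correlation. Of 77 nuclear OXPHOS subunits 1 was lower, or 54 adjusted over the list alone (median log2 -0.45), with a camera adjusted p = 1.17e-17 and an adjusted p = 0.927 with an estimated correlation. On log2 CPM the median of that list was -0.42, and -0.26 without WT vehicle mouse 2. The other lists called (camera adjusted p of 0.0417 or lower) had 0 or 1 called members higher and 0 or 1 lower, and each had an adjusted p = 0.927 with an estimated correlation. They were the neutrophil (median 1.61) and inflammatory (0.75) lists, which were higher, and the MHC class II (-1.26), immediate early (-0.44) and PPAR and fasting (-0.43) lists, which were lower. Without WT vehicle mouse 1 the calls of the neutrophil (0.0649), inflammatory (0.123) and PPAR and fasting (0.135) lists were lost, the last also without KO vehicle mouse veh_3394 (0.0606) or veh_3395 (0.0625). Of 20 glucocorticoid targets 3 were higher and 1 lower, with Zbtb16 at log2 2.22 (adjusted p = 0.0153) and Fkbp5 at 1.75 (adjusted p = 0.0302), and the list did not pass camera (adjusted p = 0.32). Cdkn1a was lower (log2 -1.36, adjusted p = 0.0447).

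The gene farthest apart was Atp6v0c-ps2, a processed pseudogene of a proton pump subunit (chromosome 6, 37806086 to 37806550), with 1627 counts summed over the KO vehicle libraries and 3 over the WT vehicle libraries (adjusted p = 6.37e-07). Its parent gene Atp6v0c (chromosome 17, 24163866 to 24169702) was lower, at 6.87 ± 0.739 CPM in KO and 37.6 ± 3.36 in WT (log2 -2.45, adjusted p = 0.0115). Counts of a gene and its pseudogene can be split by the counting, and their sum was 28.2 CPM in KO and 37.7 in WT. Tmem181a (chromosome 17, 6256860 to 6308314) was lower in KO (2.14 ± 0.0492 against 6.26 ± 0.106 CPM, log2 -1.55, adjusted p = 0.000276). Within 10 Mb on either side of Pde10a, 8 of 85 tested genes (9.41%) were called under vehicle, against 411 of 14599 others (2.82%; Fisher's exact test, two-sided, p = 0.00291). Under DOX these were 3 of 85 (3.53%) and 56 of 14599 (0.384%; Fisher's exact test, two-sided, p = 0.00482). The 3 were Rsph3b, Tmem181a and its pseudogene Tmem181c-ps, whose counts can be split by the counting. With that pair counted once these were 2 of 84 under DOX (2.38%; Fisher's exact test, two-sided, p = 0.0435) and 7 of 84 under vehicle (8.33%, p = 0.00995). Neighbouring genes are not independent. For the DOX effect in WT the shares were 20% and 18.6% (Fisher's exact test, p = 0.779).

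The count of 425 was 5186 with limma-voom, 2088 without a filter, 1682 with DESeq2, 222 in a fit of the 2 vehicle groups, 211 with the title suffix as a covariate and 68 without KO vehicle mouse veh_3394 and KO DOX mouse 18. It was 2670, 109 and 51 without WT vehicle mice 1, 2 and 3, and 42, 52 and 45 without KO vehicle mice veh_3393, veh_3394 and veh_3395. Of 36 genes named by the rule and called, 7 kept their call in each of those 6 fits: Pde10a, Atp6v0c-ps2, Arntl, Col5a3, Tmem181a, Kcnh2 and Hlf. The other 29 lost it in at least 1: 28 without KO vehicle mouse veh_3393, 28 without veh_3395, 26 without veh_3394, 27 without WT vehicle mouse 3 and 22 without mouse 2. In the fit of the 2 vehicle groups, 25 of the 35 named genes it held kept their call. With the title suffix as a covariate 25 of 36 kept it.

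**Figure D3:**
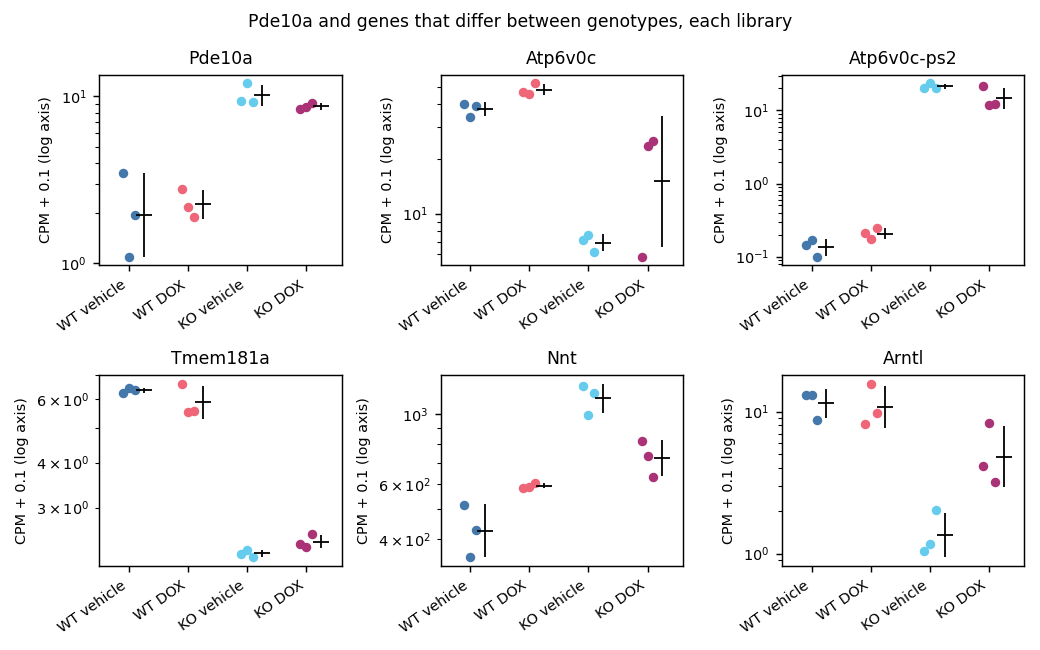
CPM plus 0.1 on a log axis for Pde10a, Atp6v0c, Atp6v0c-ps2, Tmem181a, Nnt (chosen after its values were seen) and Arntl, with each dot 1 of 3 libraries per group and the black mark and bar the mean and SD of the log values. Pde10a averaged 10.1 CPM in KO vehicle and 2.08 CPM in WT vehicle hearts; Atp6v0c in KO DOX hearts lay at 5.71, 23.4 and 24.9 CPM.

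Among DOX-treated hearts, those labelled KO differed from those labelled WT in 62 genes, 28 higher and 34 lower. Cdkn1a was lower in KO, at 26.4 ± 5.97 against 129 ± 47.2 CPM (log2 -2.29, SE 0.32, adjusted p = 0.0155), and it was the called member among 39 p53 targets, where 7 were lower and 1 higher adjusted over the list alone. The p53 list had a camera adjusted p = 0.00897, and an adjusted p = 0.255 with an estimated correlation. The nuclear receptor genes Nr4a1 (log2 -2.48, adjusted p = 0.0186) and Nr4a3 (-3.14, adjusted p = 0.0268), which respond early to stimulation, were lower, and 10 of 24 immediate early genes were lower adjusted over the list alone. That list had a camera adjusted p = 4.04e-09, and an adjusted p = 0.285 with an estimated correlation. Of 9 neutrophil markers 2 were lower, or 8 adjusted over the list alone: S100a8 (log2 -2.90, adjusted p = 0.0359) and S100a9 (-2.43, adjusted p = 0.0411). The list had a camera adjusted p = 4.81e-09, and an adjusted p = 0.255 with an estimated correlation. Glucocorticoid targets were lower (median -0.73, 11 of 20 adjusted over the list alone, adjusted p = 0.255 with an estimated correlation), as were PPAR and fasting targets (-0.70, 11 of 19 lower and 1 higher adjusted over the list alone, adjusted p = 0.478 with an estimated correlation). Pdk4, in that list and chosen after its values were seen, stood at 3240 CPM in WT DOX mouse 22 and at 246 and 412 CPM in mice 21 and 24. Oxidative stress defence genes were lower (median -0.36, adjusted p = 0.5 with an estimated correlation), with Nfe2l2, which encodes the regulator NRF2, at log2 -0.72 (adjusted p = 0.0385). The clock output genes Dbp (log2 2.03, adjusted p = 0.0484) and Hlf (1.00, adjusted p = 0.0268) were higher, and the clock list did not pass camera (adjusted p = 0.0559).

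The further lists called under DOX had camera adjusted p-values of 0.0171 or lower. Lower in KO were the unfolded protein response (median -0.38, adjusted p = 0.523 with an estimated correlation), atrophy and ubiquitin ligases (-0.35, adjusted p = 0.601 with an estimated correlation) and inflammatory genes (-0.26, adjusted p = 0.671 with an estimated correlation). Interferon response (-0.26), macrophage (-0.29) and fatty acid oxidation (-0.15) lists were also lower, each with an adjusted p = 0.715 with an estimated correlation. Calcium handling and ion channel genes (0.22, adjusted p = 0.255 with an estimated correlation), smooth muscle and pericyte markers (0.30, adjusted p = 0.285 with an estimated correlation) and fibroblast markers (0.44, adjusted p = 0.737 with an estimated correlation) were higher. Erythroid markers were higher (median 5.40, 6 of 9 adjusted over the list alone, adjusted p = 0.324 with an estimated correlation), and hemoglobin stood at 13 counts in KO DOX mouse 18. Atrial markers were higher (median 1.27, adjusted p = 0.715 with an estimated correlation). Myl7, an atrial myosin light chain also chosen after its values were seen, stood at 543 CPM in KO DOX mouse 18 and 542 CPM in KO vehicle mouse veh_3394, and at or below 14 CPM in the other 10 libraries. Without KO DOX mouse 18 the calls of the fibroblast (camera adjusted p = 0.869), atrial (0.402) and fatty acid oxidation (0.346) lists were lost, and without KO DOX mouse 19 those of the inflammatory (0.404), macrophage (0.118) and interferon (0.0735) lists. Without WT DOX mouse 22 the fatty acid oxidation (0.746), interferon (0.35), inflammatory (0.0783) and atrophy (0.0572) calls were lost, without mouse 21 the unfolded protein response and atrial calls (both 0.0874), and without mouse 24 the fibroblast call (0.259).

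The count of 62 was 1152 without a filter, 990 with limma-voom, 473 with DESeq2, 5 in a fit of the 2 DOX groups and 24 without KO vehicle mouse veh_3394 and KO DOX mouse 18. It was 727 and 12 without WT DOX mice 21 and 22, and 35, 17 and 8 without KO DOX mice 18, 19 and 20. Of 20 genes named by the rule and called, Atp6v0c-ps2, Wdfy1, Gstt2 and Tmem181a kept their call in all 6 leave-one-out fits. The other 16 lost it in at least 1: 16 without KO DOX mouse 20, 13 without mouse 19, 11 without mouse 18, and 14 and 7 without WT DOX mice 22 and 24. In the fit of the 2 DOX groups, 3 of the 20 kept their call. With the title suffix as a covariate 19 of 20 kept it.

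Of the 62 genes, 37 were also called for DOX in WT, each with the opposite sign. Independent lists would share 3.19 genes higher with DOX and lower in KO, where 25 were seen, and 2.57 in the other direction, where 12 were seen. Both comparisons use the WT DOX libraries with opposite signs. Simulated unchanged groups had opposite signs in 66.4% of all genes, against 64.3% observed. The covariance of the fold changes was -0.171, and -0.044 in the simulation. The simulation drew each gene separately, so it lacked any shift of the shared libraries across many genes. With 3 libraries the WT DOX group cannot be split, so part or all of the excess may come from the shared libraries. The count of 37 was 247 with DESeq2, 547, 3 and 16 without WT DOX mice 21, 22 and 24, 16, 5 and 2 without KO DOX mice 18, 19 and 20, and 19 and 22 without WT vehicle mice 2 and 3.

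The DOX effect differed between genotypes in 31 genes by the interaction test, 16 with a higher and 15 with a lower effect in KO. Differences were lowest for S100a8 (log2 -4.84, SE 0.77, adjusted p = 0.0288) and S100a9 (-4.34, SE 0.67, adjusted p = 0.0288). Next came Hif3a, a member of the hypoxia-inducible factor family (-3.11), and the interferon-inducible gene Ifi205 (-1.84), both with adjusted p = 0.0288, and the glutathione transferase gene Gsta3 (-2.04, adjusted p = 0.0152). Gsta3 stood at 5.07 ± 1.01 and 12.4 ± 3.03 CPM in WT and at 14.2 ± 0.887 and 8.45 ± 0.128 CPM in KO, with vehicle and DOX. Differences were highest for Aqp7, a water and glycerol channel gene (2.21, adjusted p = 0.0288), the adenosine receptor gene Adora2a (1.66, adjusted p = 0.0341) and Col5a3, a collagen gene (1.57, adjusted p = 0.0481). Il16 (1.43) and the cytokine gene Flt3l (1.30) followed, both with adjusted p = 0.0288. Aqp7 stood at 27.6 ± 7.6 and 9.31 ± 2.65 CPM in WT and at 9.89 ± 0.626 and 15.4 ± 2.97 CPM in KO. Camera called 14 lists for the interaction, and 0 passed with an estimated correlation.

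The count of 31 was 2048 with limma-voom, 1093 without a filter, 373 with DESeq2, 51 without TMM scaling and 2 without KO vehicle mouse veh_3394 and KO DOX mouse 18. Without WT vehicle mice 1, 2 and 3 it was 52, 8 and 1, without WT DOX mice 21, 22 and 24 it was 515, 3 and 6, without KO vehicle mice veh_3393, veh_3394 and veh_3395 it was 2, 3 and 2, and without KO DOX mice 18, 19 and 20 it was 72, 8 and 0. None of the 10 genes named kept its call in all 12 of those fits, and all 10 lost it without WT vehicle mouse 3, KO vehicle mouse veh_3393 or veh_3395, or KO DOX mouse 20. In the fit without both veh_3394 and KO DOX mouse 18, all 10 lost it as well.

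**Figure D4:**
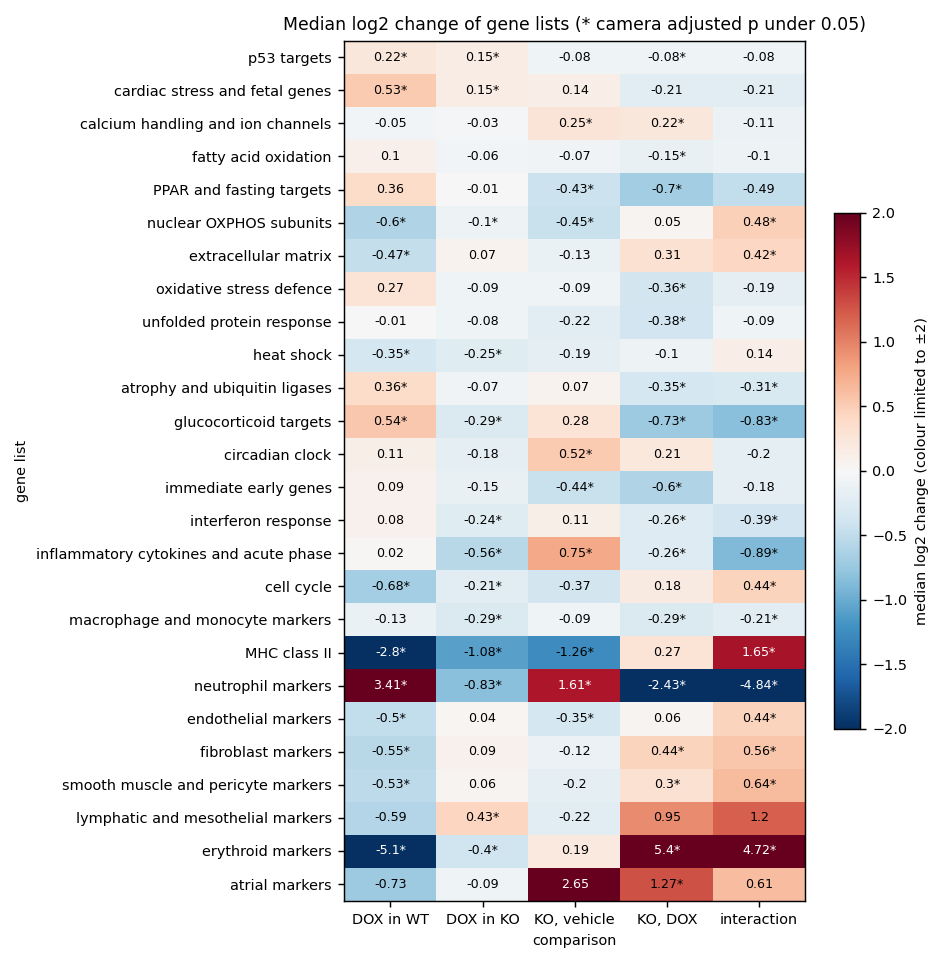
Median log2 change of each of the 26 gene lists that camera called in at least 1 comparison, for the 5 comparisons, with the value printed in each cell, the colour limited to 2 in either direction and a star for a camera adjusted p under 0.05 with the preset correlation. The neutrophil list had a median of 3.41 for DOX in WT and -0.83 for DOX in KO; no call held with an estimated correlation.

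**Figure D5:**
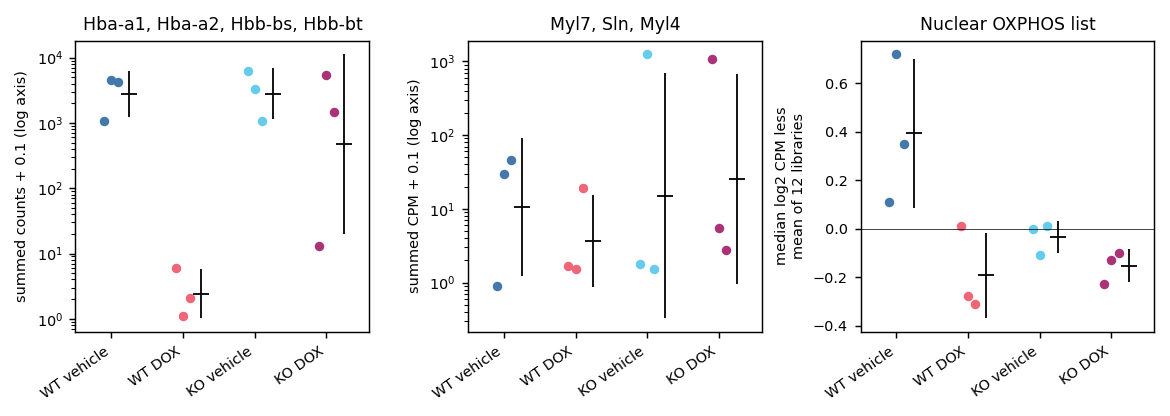
Per library, summed hemoglobin counts plus 0.1 on a log axis (left), summed CPM plus 0.1 of the atrial genes Myl7, Sln and Myl4 on a log axis (middle) and the median log2 distance of nuclear OXPHOS subunits from the mean of 12 libraries (right), with dots for libraries and bars for mean and SD. Hemoglobin counts were 6, 1 and 2 in WT DOX hearts, and the atrial genes summed to 1260 CPM in KO vehicle mouse veh_3394 and 1090 CPM in KO DOX mouse 18.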

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

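The overlap of the KO effect under vehicle with the DOX effect in WT, the test of displacement that rests on it, and the spread under regrouping, were chosen after the data were seen. The labels give groups of 3 mice, too few for a test of a sample far from the others, so the results here are those whose DOX effect differed between the genotypes as labelled, by the interaction test.

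Genes with a lower DOX effect in KO were S100a8 (log2 difference -4.84), S100a9 (-4.34), Hif3a (-3.11), Gsta3 (-2.04) and Ifi205 (-1.84). Those with a higher one were Aqp7 (2.21), Adora2a (1.66), Col5a3 (1.57), Il16 (1.43) and Flt3l (1.30). Genotype labels were regrouped within each treatment 100 times, the real grouping included, and 2 of the 100 called as many genes as the real one (31). This does not settle whether chance can be excluded, since regrouping puts the differences between the genotypes into the spread within groups: the biological coefficient of variation was 17.5% in the real grouping and above it in all 99 others (median 20.8%), and 94 of these called 0 genes. The highest other grouping called 234 genes. It exchanged only the genotype labels of WT DOX mouse 21 and KO DOX mouse 19, and a count several times the real one points to a structure of the samples, the source of which was not tested. Tmem181c-ps had no count in WT DOX mouse 21 and 2.23 CPM in KO DOX mouse 19, as in the other mice of each labelled genotype, where WT libraries had no count and KO libraries at least 1.37 CPM.

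Lists with a lower DOX effect in KO, by camera, were neutrophil markers (median log2 difference -4.84), inflammatory genes (-0.89), glucocorticoid targets (-0.83), interferon response (-0.39), atrophy and ubiquitin ligases (-0.31) and macrophage markers (-0.21). Higher ones were erythroid markers (4.72), MHC class II (1.65), smooth muscle and pericyte markers (0.64), fibroblast markers (0.56), nuclear OXPHOS subunits (0.48), cell cycle genes (0.44), endothelial markers (0.44) and extracellular matrix (0.42). Their adjusted p-values were 0.36 or higher with an estimated correlation. The erythroid call was lost without WT vehicle mouse 1 (0.0876) or 3 (0.0729), WT DOX mouse 21 (0.0709), KO vehicle mouse veh_3395 (0.0919) or KO DOX mouse 19 (0.109) or 20 (0.072). The extracellular matrix call was lost without WT vehicle mouse 1 (0.0624) or 2 (0.147), WT DOX mouse 24 (0.291), KO vehicle mouse veh_3393 (0.108) or veh_3395 (0.242) or KO DOX mouse 18 (0.714). Without KO DOX mouse 18 the fibroblast (0.191) and cell cycle (0.0632) calls were lost, the latter also without WT vehicle mouse 2 (0.186) or WT DOX mouse 21 (0.064). Without WT vehicle mouse 1 the macrophage (0.304) and interferon (0.0566) calls were lost, as they were without WT DOX mouse 22 (0.0534 and 0.0738), and the macrophage call also without KO DOX mouse 19 (0.11) or 20 (0.0549). Of the 100 groupings, 52 called as many lists as the real one (14) and the highest other called 20, so chance cannot be excluded for the number of lists.

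The low number of genes called for DOX in KO (2, against 2743 in WT) was weighed further. Larger spread between KO replicates is argued against for the typical gene, as the median SD of log2 CPM within the KO groups was 0.659 times that in the WT groups. The mean over genes of the variance divided by the number of libraries was 0.035 in KO vehicle and 0.0483 in KO DOX hearts. In WT vehicle and WT DOX hearts it was 0.0451 and 0.0401. The fit shared its spread among the 4 groups, so WT spread also entered the KO test, and its part in the low count was not tested. KO DOX mice without an effective dose were weighed by a score over 2738 genes called in WT, erythroid genes left out, measured from the KO vehicle mean. The lowest KO DOX library scored 0.039 and the highest KO vehicle library 0.011 (SD of the KO vehicle scores 0.00929). The WT vehicle libraries, also untreated, scored -0.198, -0.589 and -0.34. That range is wider than the margin between KO DOX and KO vehicle libraries, so the score cannot decide whether the dose was effective. Other values leave that margin narrow: 75.5% of those genes had the sign of WT in the real split and 74% in the highest of the other splits, hemoglobin in KO DOX mice 19 and 20 (5478 and 1497 counts) lay among the vehicle libraries and far above WT DOX hearts (6, 1 and 2), and WT DOX mouse 21 scored 0.123, within the KO DOX range of 0.039 to 0.135. KO vehicle hearts that already lay toward the WT DOX state are a candidate explanation that the test cannot decide. The covariance of the KO effect under vehicle with the DOX effect in WT was 0.142, which exceeded that of simulated unchanged groups (0.0461) by 0.0959. The simulation drew each gene separately, so it lacked any shift of the shared WT vehicle libraries across many genes. Log2 changes in both comparisons correlated with exon length (Spearman 0.364 for KO under vehicle and 0.352 for DOX in WT). The excess therefore cannot tell displaced KO vehicle hearts from shifted WT vehicle libraries.

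For that overlap, 215 genes were called in both with the same sign, 133 higher and 82 lower, where independent lists would share 24.8 and 14.8, and r was 0.481 against 0.507 in the simulation. Both comparisons use the 3 WT vehicle libraries, which are too few to split, so part or all of the excess may come from them. The count was 1858, 31 and 16 without WT vehicle mice 1, 2 and 3, 44 and 45 without WT DOX mice 22 and 24, and 17, 21 and 20 without KO vehicle mice veh_3393, veh_3394 and veh_3395. A response that depends on genotype stays open.

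A comparison of 3 against 3 has 10 splits, too few for a share under 0.05. The real split called 2743 genes for DOX in WT and the highest other 0. These were 2 and 1 for DOX in KO, 425 and 0 for KO under vehicle, and 62 and 47 for KO under DOX; in each, 1 of the 10 splits, the real one, reached the real count. The 47 came from the exchange of WT DOX mouse 21 and KO DOX mouse 19. For lists, the real and the highest other split called 14 and 19 for DOX in WT, 13 and 20 for DOX in KO, 9 and 16 for KO under vehicle, and 17 and 20 for KO under DOX. As many lists as in the real split were called in 5, 5, 7 and 5 of the 10 splits.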

How the results depend on the processing

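The fits without KO vehicle mouse veh_3394 and KO DOX mouse 18, the overlap of the KO effect under vehicle with the DOX effect in WT, and the count near Pde10a with the Tmem181a pair counted once, were added after seeing the data; the other alternatives were fixed before. No called value of a named gene changed sign under them, and no called list did under those run for lists: DESeq2's size factors, the 1 CPM filter, an estimated correlation, fry and left-out libraries. With DESeq2's size factors in edgeR, and with a filter of 1 CPM in 3 libraries, all 5 gene counts stayed within 1.5 times their value. For DOX in WT (2743 genes), 5575 were called with limma-voom, 1595 with the title suffix as covariate, 20 with the 2 groups compared only, and 183 to 4188 leaving out 1 library. For DOX in KO (2), 309 were called without a filter, 66 with DESeq2, 88 with limma-voom, 0 without TMM scaling, 0 with the suffix, 0 with the 2 groups only, 1 without mice veh_3394 and 18, and 0 to 4 leaving out 1. For KO under vehicle (425), these were 2088 without a filter, 211 with the suffix, 1682 with DESeq2, 5186 with limma-voom, 222 with the 2 groups only, 68 without mice veh_3394 and 18, and 42 to 2670 leaving out 1. For KO under DOX (62), they were 1152 without a filter, 473 with DESeq2, 990 with limma-voom, 5 with the 2 groups only, 24 without mice veh_3394 and 18, and 8 to 727 leaving out 1. For the interaction (31), they were 51 without TMM scaling, 1093 without a filter, 373 with DESeq2, 2048 with limma-voom, 2 without mice veh_3394 and 18, and 0 to 515 leaving out 1. Of the genes called by limma-voom and DESeq2 for KO under vehicle, 425 and 396 were among the 425. Fewer libraries in the fit leave fewer degrees of freedom; why some libraries, such as WT vehicle mouse 1, raise the counts when left out was not tested, and neither was the cause of the other changes.

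Gene lists called by camera numbered 14, 13, 9, 17 and 14 for DOX in WT, DOX in KO, KO under vehicle, KO under DOX and the interaction. With an estimated correlation they numbered 0, 0, 0, 0 and 0, and with fry 9, 0, 2, 3 and 0. Of the 9 with fry in WT, 8 were among the 14. Leaving out 1 library gave 9 to 16 for DOX in WT, 8 to 22 for DOX in KO, 6 to 12 for KO under vehicle, 13 to 20 for KO under DOX and 10 to 18 for the interaction. Without mice veh_3394 and 18 there were 13, 11, 11, 18 and 14.

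The Pearson r between the DOX effects (0.143) was 0.206 with the 1 CPM filter, 0.145 without mice veh_3394 and 18, and 0.0398 to 0.179 leaving out 1 library, the lowest without KO vehicle mouse veh_3394. Genes called in opposite directions for DOX in WT and KO under DOX (37) numbered 247 with DESeq2 and 2 to 547 leaving out 1. Genes called in the same direction for DOX in WT and KO under vehicle (215) numbered 892 with DESeq2 and 16 to 1858 leaving out 1. The excess of calls near Pde10a held in windows of 5 Mb (p = 0.000103 under vehicle and 0.00118 under DOX, Fisher's exact test) and 20 Mb (3.33e-07 and 0.000551), and with the Tmem181a pair counted once within 10 Mb (7 genes, p = 0.00995, and 2 genes, p = 0.0435). These windows are nested, so they are not separate checks. Under vehicle the same 8 genes were called within 5 Mb (of 52 tested) and within 10 Mb (of 85), and 24 of 256 within 20 Mb. Pde10a kept its difference with DESeq2's size factors (log2 2.29 and 1.98). The sex covariate was not run because 1 sex was present, and no paired analysis was possible because the groups share no animal number. With totals of 23846398 to 32921876 counts, genes under 1 CPM rest on few reads.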

Other observations

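The tests of sarcomere genes, of the markers of other cell types, of the gene and pseudogene sums, of the neighbourhood of Pde10a, and of length, GC content and WT vehicle mouse 2 for the KO vehicle hearts, were chosen after the values were seen. No clock gene was called for DOX in KO, and the clock list did not pass camera there (adjusted p = 0.913). Arntl (log2 1.98 for DOX in KO, adjusted p = 0.246) stood at 0.95, 1.06 and 1.92 CPM in KO vehicle hearts, 4.02, 8.27 and 3.12 CPM in KO DOX hearts and between 8.09 and 15.7 CPM in WT hearts. Dbp, Hlf and Per3 averaged 123, 45.2 and 52.4 CPM in KO vehicle hearts and 70, 19.3 and 23.2 CPM in WT vehicle hearts. In KO DOX hearts Dbp stood at 107, 98.4 and 121 CPM, overlapping the KO vehicle hearts (128, 133 and 109 CPM). The labels used here give no time of collection.

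Hemoglobin transcripts were nearly absent (1 to 13 counts) in WT DOX mice 21, 22 and 24 and KO DOX mouse 18, and held 1057 to 6310 counts in the other 8 libraries, KO DOX mice 19 and 20 among them. Alas2, the erythroid heme synthesis enzyme gene, followed the same division, with 0.197 CPM or less in those 4 libraries and at least 1.41 CPM elsewhere. Myl7, Sln and Myl4, chosen after their values were seen, were high in KO vehicle mouse veh_3394 (542, 110 and 612 CPM) and KO DOX mouse 18 (543, 80.1 and 465 CPM). Pdk4, a gene of fasting metabolism, stood at 3240 CPM in WT DOX mouse 22, against at most 626 CPM in the other libraries.

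The lower nuclear OXPHOS transcripts in WT DOX and KO vehicle hearts than in WT vehicle hearts were weighed against technical explanations. Transcript length and GC content as the whole cause are argued against: on log2 CPM the median change in WT was -0.59 before and -0.36 after adjusting each library for both (quartiles -0.53 and -0.23 after) and that in KO under vehicle -0.42 and -0.33 (quartiles -0.41 and -0.21 after), though they accounted for 18.6% of the variance of WT vehicle mouse 2's deviations. They accounted for 8.55% in mouse 3 and 0.246% in mouse 1, the same order as the list's medians in these mice (0.72, 0.35 and 0.11). Across genes with a known length, the log2 change had a Spearman correlation with exon length of 0.352 for DOX in WT. It was 0.364 for KO under vehicle. Length was that of all annotated exons of a gene together, and GC content that of its longest transcript. The lengths of the transcripts present in these hearts were not known, so the adjustment may correct too little. This limits the argument against length and GC content as the whole cause. WT vehicle mouse 2 as the whole cause is argued against by medians without it of -0.42 in WT (quartiles -0.51 and -0.27) and -0.26 in KO under vehicle (quartiles -0.34 and -0.16), where its absence took the median from -0.42. Those medians kept mouse 3, in which the list also stood high. On the scale of the list's medians WT vehicle mouse 1 stood at 0.11 and KO vehicle libraries at 0, -0.11 and 0.01. WT DOX mice 21, 22 and 24 stood at 0.01, -0.28 and -0.31. Set against mouse 1 alone the gaps are thus smaller, above all for KO vehicle hearts and WT DOX mouse 21. The adjustment for length and GC content and the removal of mouse 2 were not made together, so their joint part was not tested. A lower share of cardiomyocyte RNA would lower the sarcomere list as well, and in WT that list did not fall as a whole (median 0.18, quartiles -0.28 and 0.33). The sarcomere values were not adjusted for length and GC content. They therefore argue against a lower share in WT on unadjusted values only, and whether this holds after adjustment was not tested. Under vehicle in KO, a lower share as the only change is argued against by markers of other cell types, which it would raise alike. These moved apart: endothelial markers had a median of -0.35 (quartiles -0.57 and -0.26) and neutrophil markers 1.44 (quartiles 1.22 and 1.78). The neutrophil call was lost without WT vehicle mouse 1 (camera adjusted p = 0.0649). A lower share beside shifts of single cell types cannot be told apart there, and the sarcomere list (-0.01, quartiles -0.36 and 0.20) did not decide. A change in the hearts themselves stays open, and the list's call was lost with an estimated correlation.

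Some genes near Pde10a (8 of 85 under vehicle and 3 under DOX) and at the pseudogenes named differed in the libraries labelled KO. A chromosome segment of another strain around the targeted allele is a candidate explanation for the genes near Pde10a, as calls within 10 Mb were in excess under vehicle (Fisher's exact test, two-sided, p = 0.00291, or 0.00995 with the Tmem181a pair counted once) and for DOX in WT they were not (p = 0.779), while under DOX in KO against WT the excess rests on 2 genes with the pair counted once (p = 0.0435). It would not cover genes on other chromosomes that also separated every KO from every WT library. Wdfy1 (chromosome 1) stood at 23.7 to 26.8 CPM in KO and 7.94 to 10.9 CPM in WT libraries. Nnt (chromosome 13, chosen after its values were seen) stood at 632 to 1220 CPM in KO and 352 to 603 CPM in WT libraries. Descent of the mice beyond such a segment was not tested and cannot be told apart from PDE10A loss between KO and WT. Reads moving between Atp6v0c and its pseudogene may account for part of that pair's difference under vehicle, where the summed counts differed by -0.42 on the log2 scale against -2.45 for the gene, but under DOX (-0.54 against -1.42) they cannot be told apart from a real difference, because -0.54 lies between the bounds used, within 0.5 of 0 and beyond 1. For Tmem181a and Tmem181c-ps, which had no count in any WT library, the sum differed by -0.62 under vehicle, between the same bounds, so that shared reads cannot be told apart from a real difference there, and by -0.39 under DOX, where they may account for part of it. An effect of PDE10A loss on its neighbours was not tested.

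For 3 other genes, chosen after their values were seen, values are given for the KO groups, although none was called for DOX in KO (adjusted p = 0.493 for Atp6v0c, 0.306 for Nnt and 0.132 for 6430562O15Rik). Atp6v0c stood at 6.06 to 7.51 CPM in KO vehicle hearts and 5.71 CPM in KO DOX mouse 18, at 23.4 and 24.9 CPM in KO DOX mice 19 and 20, and at 33.8 to 52.1 CPM in WT hearts. Nnt, in which the C57BL/6J strain is known to carry a deletion, averaged 1120 ± 118 CPM in KO vehicle hearts, 728 ± 93.3 in KO DOX, 432 ± 81.4 in WT vehicle and 591 ± 10.8 in WT DOX hearts (n = 3 each). The transcript 6430562O15Rik had no count in the KO vehicle libraries and 0.439 to 1.77 CPM in KO DOX hearts. These values are given without a test of the animals' descent, which the labels used here do not record.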
